A study of Mus musculus with 24 samples.

How the data were processed

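RNA of extracellular vesicles precipitated from plasma was measured in 24 libraries of mouse, 1 per animal, in 4 groups of 6: bile duct ligation or sham surgery, each at day 8 or day 15. Per the labels' protocols, vesicles were precipitated with ExoQuick, RNA was extracted with a miRNeasy kit, and libraries were made with the TruSeq stranded mRNA kit without ribosomal RNA depletion or poly(A) selection and amplified by PCR. The tissue label of every sample reads liver while the site label reads extracellular vesicles, and the protocol text describes plasma vesicles, so the values were read as vesicle RNA. The treatment text names ligation for sham samples too; the groups were taken from the sample titles, which the treatment labels match.

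The deposited table holds expected counts per gene for 21960 genes and 24 libraries, and all of its values are whole numbers. Per the submitters' processing notes, STAR and RSEM were used; their versions are not given in the sources used here. RSEM estimates counts that need not be whole, so the values were taken to be expected counts rounded before deposit, and who rounded them is not given in the sources used here. The same notes name the human build hg38, whereas the identifiers are mouse Ensembl genes, so the build used for alignment was not established. Of the 21960 identifiers, 21860 were found in the GENCODE M21 annotation of GRCm38, 21665 of them as protein-coding genes, and every coordinate printed comes from that annotation by identifier. Non-coding and mitochondrially encoded genes were nearly or fully absent from the table, so shares of counts are shares of the counts in this table, not of all reads. How RSEM divided reads among near-identical genes and between strands is not given in the sources used here, and single members of the satellite-like gene family described in the results are uncertain for that reason.

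Total counts ran from 101733 to 937963 per library. The day 8 libraries numbered 4 to 6 were deeper than those numbered 1 to 3 in both groups. Libraries of the same group differed beyond sampling noise, with a chi-square per degree of freedom of 1.66 or more between any 2 of them, so none was treated as a repeat of another. Reads carry no molecular identifiers, so binomial intervals (95%, exact Clopper-Pearson), exact intervals of count ratios and detection floors (3 counts over a group) cover counting error only.

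Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 4112 genes. A gene could pass this filter through the libraries of a single group. Fractions of list members that rose or fell are therefore fractions of the members it kept. Counts were normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, 1 mean per group, all 24 libraries in the model, no further covariate), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Comparisons were ligation against sham at day 8, at day 15 and averaged over both days, the difference of the ligation effect between days, and day 15 against day 8 within each treatment. All fold changes are log2 values with standard errors (SE). Genes without a count in the group compared against are given as lower bounds against the floor, and genes with 1 to 3 counts as a ratio of normalised counts with its exact interval.

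The gene lists numbered 29, written down before the data were examined together with the groups, tests, alternatives and the rule for naming genes. Lists with at least 5 tested genes, 20 in all, were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's genes move, on balance, 1 way without comparing them with other genes. Shares of counts were tested for 27 lists by a two-sided exact permutation test of 6 against 6 (924 arrangements, smallest p 0.00216); the lists of mitochondrially encoded genes and small nuclear RNAs had 0 genes in the table. The list of structural RNAs held Lars2 alone. Shares were put on a log2 scale after adding 0.5 counts. Named genes were, for each day, the 8 with the largest change in each direction among called genes with a mean of at least 5 CPM, up to 3 called members of each list by smallest p, and 9 genes set in advance where tested; for comparisons of times and for the difference between days, the 5 with the smallest p. Predicted genes were counted and not named, except where a sentence says that a gene was chosen after its values were seen. Some genes that the rule names are not reported here.

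The titles number the animals of each group 1 to 6. Deviations from the group means correlated between ligation and sham libraries of the same number by 0.165 to 0.327 at day 8, with 6 of 6 numbers over 0.1, and by -0.031 to 0.113 at day 15, with 1 of 6 over 0.1. The pairing rests on these data alone. By the criterion set beforehand the numbers pair the libraries of day 8 and not those of day 15, and a replicate block was an alternative. The best match was the same number for only 3 of 6 numbers at day 8 and 1 of 6 at day 15. Numbers 1, 5 and 6 of day 8 matched best with 3, 6 and 4, within libraries 1 to 3 or within the deeper libraries 4 to 6. Pairing by number could therefore not be told apart from that split in depth.

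Alternatives were RLE size factors, no filter and a stricter filter (10 counts in 12 libraries), a replicate block, hemoglobin genes and Lars2 left out, models of the 2 groups compared alone, DESeq2 1.42.0, limma with voom and quality weights, other list tests, and each library left out in turn. Chosen after the data were seen were a term for the deeper day 8 libraries, a block within days, removal of the satellite-like genes, of 3 libraries rich in them or of sham animals 2 and 3 of day 15, thinning to the smallest library, the day 8 libraries 1 to 3 or 4 to 6 alone (also for shares at day 15 against day 8), the share tests of 27 lists, list shares per TMM effective library size, and a rank correlation with zeros tied. The test of the joint share of both hepatocyte lists was written down beforehand. The tests were checked on simulated counts with 4112 genes. For day 8, 48% of genes changed 2-fold, 94% of those changed 4-fold and 100% of those changed 8-fold were called, and 8 of 179 called genes were unchanged ones. For day 15 the shares were 44%, 82% and 100%, with 4 unchanged genes among 167 calls. In both simulations the moved list was called and 0 of 20 unmoved lists were. Simulated genes were drawn independently, so this does not check list calls where genes correlate. Members of the real lists did correlate, with an estimate of 0.653 for secreted hepatocyte genes at day 8. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.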

Results

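Extracellular vesicles are membrane-enclosed particles that cells release into blood and that carry RNA. Vesicle RNA from plasma was sequenced in male C57BL/6J mice, an inbred laboratory strain, after ligation of the bile duct or a sham operation. Ligation blocks the flow of bile, which causes cholestasis and, with time, liver fibrosis. Each of the 4 groups held 6 animals, killed 8 or 15 days after surgery, and each library came from 1 animal. Total counts per library ran from 167939 to 937963 after ligation and from 101733 to 824640 after sham surgery at day 8. At day 15 they ran from 315404 to 465744 and from 157133 to 351201. The table listed 11312 ± 1431 genes with a count per library (SD, n = 24). The 4112 genes kept for testing held 92.3% ± 1.12 of the counts.

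A few genes took most of the counts in every group. The gene model of Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, GRCm38 chromosome 9, 123366927 to 123462666, plus strand), held 47.1% ± 4.19 of the counts (SD, n = 24). The list of structural RNAs, written beforehand, includes Lars2, and the libraries had no ribosomal RNA depletion or poly(A) selection. Whether these counts come from Lars2 messenger RNA or from ribosomal RNA was not tested. Hemoglobin genes held 7.82% ± 2.80. At day 8 the libraries numbered 4 to 6 were both deeper (535737 to 937963 counts, against 101733 to 349386 for numbers 1 to 3) and richer in platelet transcripts. This held in sham animals (1.47% against 0.400%) as in ligated animals (1.81% against 0.400%). The first principal component of the tested genes held 24.3% of the variance and the second 14.1%.

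The series asks whether RNA of liver cells in circulating vesicles marks early cholestatic fibrosis. Transcripts of 76 hepatocyte genes, which encode plasma proteins and enzymes of liver metabolism, made up 0.175% ± 0.166 of the counts after ligation and 0.0218% ± 0.00856 after sham surgery at day 8 (SD, n = 6 each). At day 15 they made up 1.20% ± 0.957 after ligation and 0.0271% ± 0.00785 after sham surgery. On the log2 scale the differences were 2.73 (SE 0.46) and 5.17 (SE 0.47). At both days all 6 ligated animals lay above all 6 sham animals (two-sided exact permutation p = 0.00216 each, the smallest that 6 against 6 can give). The estimated effect of ligation was larger at day 15 than at day 8 by 2.44 on the log2 scale (permutation p = 0.016, 853776 arrangements). These arrangements assume that the permuted labels have no effect at all, not that ligation acts equally on both days. This p is therefore only approximate for a difference between days. Within the shallower and the deeper libraries of day 8, the shares were 0.248% against 0.0248% and 0.102% against 0.0187%, each with an exact p of 0.1, which is the smallest that 3 against 3 can give. Ligated animal number 3 of day 8 had the highest share of its group (0.512%, 95% exact interval 0.487 to 0.538). Without it the day 8 difference of means fell from 0.153 to 0.0857 percentage points (exact p = 0.00216).

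**Figure D1:**
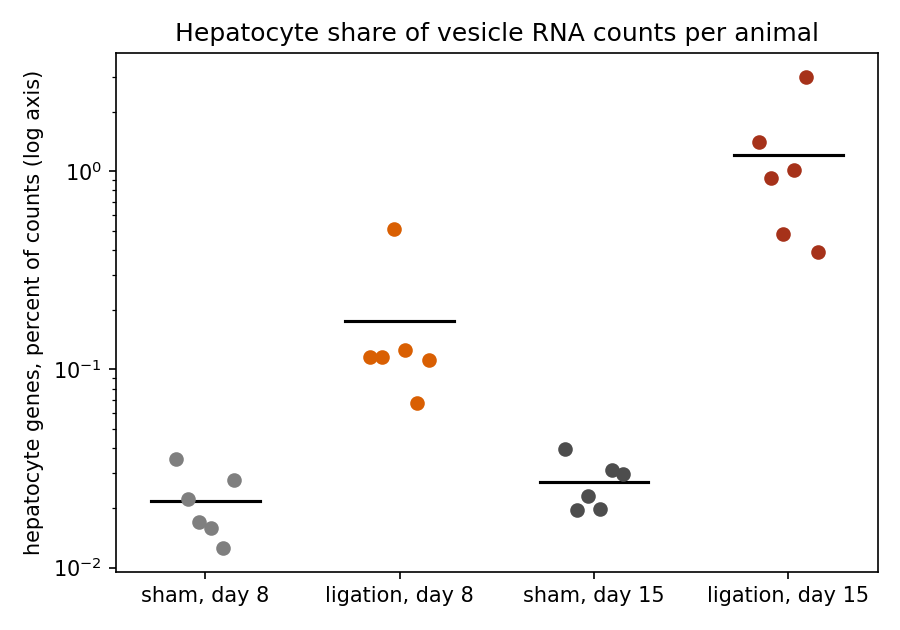
Share of counts in 76 hepatocyte genes (percent, log axis) for each animal of the 4 groups, with points for animals and bars for group means. All ligated animals lie above all sham animals of the same day, with group means of 0.175% against 0.0218% at day 8 and 1.20% against 0.0271% at day 15.

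Ligation against sham surgery at day 8 raised transcripts of plasma proteins made by hepatocytes. Hpx, which encodes the heme carrier hemopexin (ENSMUSG00000030895, chromosome 7, 105591613 to 105600137, minus strand), rose by 8.13 (SE 1.07, adjusted p = 0.00011) on the log2 scale. It went from 1 count over the 6 sham libraries to 335 after ligation, a ratio of 347 (95% exact interval 61.8 to 13700). Alb, which encodes albumin (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand), rose by 5.32 (SE 0.90, adjusted p = 0.00178), and Trf, which encodes the iron carrier transferrin, by 3.43 (SE 0.54, adjusted p = 0.000714). In all, 114 genes were higher and 15 were lower after ligation among 4112 tested (edgeR, 588 at unadjusted p under 0.05), with 6 animals per group. Leaving out ligated animal 2 gave 74 higher genes, sham animal 4 gave 52 and sham animal 5 gave 56. The lower genes numbered 8, 7, 4 and 7 without ligated animals 1, 2, 4 and 5, and 9, 5, 6 and 5 without sham animals 2, 3, 4 and 5. Where 5 or fewer were left, named after their values were seen, they were Col2a1, Actc1, Pik3c2b and Pea15a (without ligated animal 4), Col2a1, Actc1, Pik3c2b, St6gal1 and Map4k2 (without sham animal 3), and Col2a1, Actc1, Pln, Map4 and Map4k2 (without sham animal 5).

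Of the 17 tested genes for proteins that hepatocytes secrete, 12 rose at day 8 over all genes tested and 16 adjusted over the list alone. Their median log2 fold change was 4.12, or 4.06 with genes absent from sham libraries set at their lower bound (camera adjusted p = 1.32e-25, adjusted p = 0.0254 with an estimated correlation). Apob, the structural protein of lipoproteins made by the liver, had 270 counts against 3, a ratio of 93.2 (31.5 to 455). The apolipoprotein gene Apoa1 rose by 3.75 (SE 0.82, adjusted p = 0.0107). The protease inhibitor genes Serpina1b, Serpina1a and Pzp had ratios of 85.9 (15.0 to 3430), 50.7 (13.7 to 425) and 53.8 (14.5 to 450). Among 10 metabolic hepatocyte genes 3 rose, 6 adjusted over the list alone, with a median of 2.72 (camera adjusted p = 2.44e-07, adjusted p = 0.113 with an estimated correlation). They included Bhmt, with a ratio of 48.1 (13 to 403), and the cytochrome P450 gene Cyp3a11 (3.86, SE 1.06, adjusted p = 0.0474). The call of Bhmt ended without ligated animal number 3 or sham animal number 4 (log2 values of 4.30 to 5.86 over the refits that each left out 1 library), and that of Cyp3a11 in 8 of 12 such refits (2.75 to 4.70).

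Acute phase genes, whose products the liver releases during inflammation, rose in 8 of 12 tested cases at day 8 and in 12 adjusted over the list alone. Their median was 4.27, or 3.55 at the bounds (camera adjusted p = 1.03e-17, adjusted p = 0.0254 with an estimated correlation). Fgb, a fibrinogen chain, was at least 27.6-fold higher, and the hemoglobin-binding protein gene Hp rose by 3.35 (SE 0.66, adjusted p = 0.00638). Pigr, the receptor that carries immunoglobulin A across epithelia, was at least 30.4-fold higher. Of 10 complement and coagulation genes 3 rose, 5 adjusted over the list alone, with a median of 1.30 (camera adjusted p = 6.57e-06, adjusted p = 0.0722 with an estimated correlation). They were the complement genes Cfb (3.31, SE 0.72), C4b (1.93, SE 0.44) and C1s1 (2.16, SE 0.54), with adjusted p of 0.0107, 0.0171 and 0.0229. The call of C1s1 ended when ligated animal 4 or sham animal 3, 5 or 6 was left out (1.57 to 2.45). Among 5 tested genes of the bile duct list, Krt8 rose, with a ratio of 20.7 (6.75 to 103), and 3 rose adjusted over the list alone. The list did not pass (median 2.03, camera adjusted p = 0.0875, adjusted p = 0.375 with an estimated correlation). Krt8 encodes a keratin of simple epithelia that hepatocytes also express, and its call ended without ligated animal 3 or sham animal 4 or 5 (3.12 to 5.31). Krt19, the keratin of bile duct cells, had a log2 fold change of 2.12 (SE 0.89, adjusted p = 0.249). Saa1, a major acute phase gene below the filter, had 11 counts over the ligated and 0 over the sham libraries.

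Transcripts of red blood cells and myeloid cells were also higher at day 8. Of 23 erythroid genes 13 rose, 20 adjusted over the list alone, with a median of 1.08 (camera adjusted p = 5.76e-19, adjusted p = 0.0722 with an estimated correlation). Hbb-bs, a beta globin gene, rose by 1.08 (SE 0.24, adjusted p = 0.0121), and Alas2, the erythroid enzyme of heme synthesis, by 1.29 (SE 0.27, adjusted p = 0.00836). Of 8 macrophage and monocyte genes 2 rose, 5 adjusted over the list alone, with a median of 0.757 (camera adjusted p = 1.73e-05, adjusted p = 0.0448 with an estimated correlation). These were Ccr2, the chemokine receptor of inflammatory monocytes (1.94, SE 0.40, adjusted p = 0.00757), and Tyrobp (0.84, SE 0.24, adjusted p = 0.0485). The call of Tyrobp ended in 11 of 12 refits without 1 library (0.70 to 0.94). Of 9 neutrophil genes Chil3 (2.41, SE 0.68, adjusted p = 0.0474) and Retnlg (1.54, SE 0.40, adjusted p = 0.0322) rose, 7 adjusted over the list alone, with a median of 1.77 (camera adjusted p = 7.48e-07, adjusted p = 0.113 with an estimated correlation). Their calls ended in 9 (2.04 to 2.90) and 8 (1.37 to 1.70) of 12 refits. S100a8, a calcium-binding protein of neutrophils, had a log2 fold change of 2.02 (SE 0.62, adjusted p = 0.071) and passed the threshold with the replicate block (2.09).

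Lists that moved without a called member at day 8 were smaller in size. All 16 interferon response genes missed the threshold singly, 4 passed adjusted over the list alone, and their median was 0.471 (camera adjusted p = 0.00235, adjusted p = 0.259 with an estimated correlation). For 26 platelet genes the median was 0.444 (camera adjusted p = 0.0158, adjusted p = 0.603 with an estimated correlation). Pf4, platelet factor 4, had a log2 fold change of 0.42 (SE 0.31, adjusted p = 0.586). For 10 proliferation genes the median was 0.626 (camera adjusted p = 0.036, adjusted p = 0.433 with an estimated correlation). For 11 genes of oxidative and endoplasmic reticulum stress it was 0.3 (camera adjusted p = 0.00599, adjusted p = 0.143 with an estimated correlation). Adjusted over the list alone, 0 and 3 of their members were called. Within the day 8 libraries 1 to 3 and 4 to 6, the camera adjusted p was 4.21e-05 and 0.273 for the interferon list (medians 0.7 and 0.279), 0.0232 and 0.0987 for proliferation (0.68 and 0.383), and 0.216 and 0.000378 for stress genes (0.382 and 0.499). The platelet list lost its call in 6 of 12 refits without 1 library (adjusted p up to 0.375) and the proliferation list in 5 of 12 (up to 0.15).

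Genes lower after ligation at day 8 included Col2a1, Actc1 and Pln. Col2a1, the collagen of cartilage, fell by 3.96 (SE 0.84, adjusted p = 0.00861). Of 5 heart muscle genes Actc1, cardiac alpha actin, fell by 2.54 (SE 0.60, adjusted p = 0.0182) and Pln, the calcium pump regulator phospholamban, by 2.16 (SE 0.61, adjusted p = 0.0495). Adjusted over the list alone 3 were lower (median -1.31, camera adjusted p = 0.000238, adjusted p = 0.118 with an estimated correlation). With the replicate block 24 genes were lower and Pln lost its call (-2.08), as it did in 9 of 12 refits without 1 library. The call of Actc1 ended without sham animal 6 (-3.19 to -2.16 over all refits). Plcg1, a phospholipase of receptor signalling, fell by 1.05 (SE 0.26, adjusted p = 0.0241), Pik3c2b, a lipid kinase, by 1.10 (SE 0.26, adjusted p = 0.0175), and Fam43a by 1.10 (SE 0.29, adjusted p = 0.0377). Aff3, a nuclear protein of lymphoid cells, fell by 1.11 (SE 0.31, adjusted p = 0.0471), and Rflnb by 1.08 (SE 0.31, adjusted p = 0.0494). The calls of Plcg1, Fam43a, Aff3 and Rflnb ended in 4, 8, 9 and 9 of 12 refits, and that of Pik3c2b without sham animal 5 (-1.22 to -0.91).

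Of 10 B cell and plasma cell genes 0 were called by edgeR over all genes tested and 2 were lower adjusted over the list alone. Their median at day 8 was -0.746 (camera adjusted p = 5.4e-06, adjusted p = 0.113 with an estimated correlation). Of 19 genes of stellate cells and fibrosis 0 were called either way (median -0.343, camera adjusted p = 0.014, adjusted p = 0.375 with an estimated correlation). Col1a1, the main chain of type I collagen, had a log2 fold change of -0.85 (SE 0.35, adjusted p = 0.244). The median of 80 ribosomal protein genes was -0.0779 (camera adjusted p = 0.0107, adjusted p = 0.603 with an estimated correlation). Lists that did not pass were endothelial genes (16 tested, median -0.311, adjusted p = 0.0502, and adjusted p = 0.0252 with the replicate block), adipocyte genes (6, 0.224, 0.197), genes for vesicle proteins (22, 0.297, 0.0765) and histone genes (56, 0.295, 0.162), by camera. Within the day 8 libraries 1 to 3 and 4 to 6, the camera adjusted p was 0.172 and 0.00289 for the stellate cell list (medians -0.403 and -0.528), and 0.564 and 3.24e-05 for ribosomal protein genes (0.00421 and -0.179). The endothelial list passed in libraries 4 to 6 (-0.559, 0.000965), as did the vesicle protein list (0.336, 0.0251). The stellate cell list lost its call without ligated animal 5 or 6 or sham animal 2 (adjusted p up to 0.314) and the ribosomal list in 5 of 12 refits (up to 0.119).

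Ligation against sham surgery at day 15 raised hepatocyte transcripts further. Hpx rose by 10.17 (SE 1.04, adjusted p = 2.11e-07), from 1 count to 2332, a ratio of 1820 (326 to 71800). Alb rose by 7.19 (SE 0.94, adjusted p = 8.89e-06), Apob by 7.21 (SE 0.74, adjusted p = 2.11e-07) and Trf by 5.64 (SE 0.57, adjusted p = 2.11e-07). Genes with 0 counts in sham libraries were Mat1a, which makes S-adenosylmethionine (at least 169-fold), Cyp3a11 (at least 149-fold), the fibrinogen chain gene Fgg (at least 109-fold) and Serpina3k (at least 104-fold). Others were the plasma protein genes Itih3 and Itih2 (at least 92.2-fold and 66.8-fold), and Plg, which encodes plasminogen (at least 61.8-fold). In all, 143 genes were higher and 44 lower among 4112 tested (edgeR, 743 at unadjusted p under 0.05), with 6 animals per group.

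By list, 16 of 17 secreted hepatocyte genes rose at day 15 and 17 adjusted over the list alone, with a median of 6.56, or 6.41 at the bounds (camera adjusted p = 2.99e-48, adjusted p = 0.00223 with an estimated correlation). The table held 36 secreted, 40 metabolic hepatocyte and 30 acute phase genes, of which the filter kept 17, 10 and 12. Genes could be kept through ligated libraries alone, so these fractions do not describe the whole lists. Serpina1b rose by 6.41 (SE 0.71, adjusted p = 7.89e-07) and Apoa1 by 6.02 (SE 0.71, adjusted p = 2.5e-06). Of 10 metabolic hepatocyte genes 9 rose, 10 adjusted over the list alone, with a median of 5.77, or 5.50 at the bounds (camera adjusted p = 2.44e-19, adjusted p = 0.0135 with an estimated correlation). Of 12 acute phase genes 10 rose, 11 adjusted over the list alone, with a median of 6.60, or 6.29 at the bounds (camera adjusted p = 3.59e-26, adjusted p = 0.00223 with an estimated correlation). Fgb and Itih4 had ratios of 415 (74.2 to 16400) and 227 (40.4 to 8990). Of 10 complement and coagulation genes 4 rose over all genes tested and adjusted over the list alone (median 1.05, camera adjusted p = 5.34e-05, adjusted p = 0.0902 with an estimated correlation). They included Cfb (3.36, SE 0.59, adjusted p = 0.000378) and C4b (1.88, SE 0.42, adjusted p = 0.00597). Of 5 bile duct genes Krt18 (4.59, SE 0.81, adjusted p = 0.000424) and Krt8 (4.36, SE 0.82, adjusted p = 0.000931) rose, and 2 rose adjusted over the list alone (median 1.27, camera adjusted p = 0.00346, adjusted p = 0.16 with an estimated correlation). Both keratins are also expressed by hepatocytes. Krt19 had a log2 fold change of 0.86 (SE 0.68, adjusted p = 0.564).

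Genes of oxidative and endoplasmic reticulum stress rose at day 15 in 3 of 11 tested cases and in 6 adjusted over the list alone, with a median of 0.845 (camera adjusted p = 7.16e-06, adjusted p = 0.0311 with an estimated correlation). They were Gstm3 (at least 38.7-fold) and Gstm1 (1.31, SE 0.35, adjusted p = 0.0228), which encode glutathione transferases, and Srxn1, which encodes the antioxidant enzyme sulfiredoxin (1.96, SE 0.43, adjusted p = 0.00493). Hepatocytes also express both glutathione transferase genes, and the library with the highest Gstm3 value (187 CPM, ligated animal 5) had the highest hepatocyte share (3.00%, 95% exact interval 2.96 to 3.05). The call of Gstm1 ended in 5 of 12 refits without 1 library (0.88 to 1.48). Ccr2 rose by 1.96 (SE 0.44, adjusted p = 0.00686), the only called gene of the 8 on its list both over all genes tested and adjusted over the list alone (median 0.182, camera adjusted p = 0.135). The stearoyl-CoA desaturase gene Scd1 of the adipocyte list rose by 1.71 (SE 0.49, adjusted p = 0.0414), the only 1 of 6 by either adjustment (median 0.169, camera adjusted p = 0.464). Hspa8, a chaperone found in vesicles, rose by 0.54 (SE 0.14, adjusted p = 0.0226), with 3 of 22 vesicle protein genes called adjusted over the list alone (median 0.138, camera adjusted p = 0.179). The call of Scd1 ended in 7 of 12 refits (1.42 to 2.32) and that of Hspa8 in 4 (0.49 to 0.59). Xpo7, a nuclear export receptor of the erythroid list, rose by 1.48 (SE 0.41, adjusted p = 0.0298) and lost its call in 8 of 12 refits (1.29 to 1.81). It was the only call among 23 erythroid genes by either adjustment (median 0.263, camera direction up, adjusted p = 0.0377, adjusted p = 0.686 with an estimated correlation). As a share of counts the erythroid list went the other way, at 6.71% against 8.08% (log2 difference -0.27, exact permutation p = 0.312). Without sham animals 2 and 3, 12 erythroid genes were higher adjusted over the list alone (median 0.653, camera adjusted p = 5.04e-08). Hbb-bs had a log2 fold change of -0.03 (SE 0.24, adjusted p = 0.965).

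Genes lower after ligation at day 15 included Col1a1, Col6a2, Col15a1, Mcm3, Mcm7 and Hist1h4c. Of 19 genes of stellate cells and fibrosis 4 fell and 8 were lower adjusted over the list alone. Fn1, which encodes fibronectin and is expressed by hepatocytes too, rose by 1.56 (SE 0.36, adjusted p = 0.00842), the only higher call by either adjustment (median -0.807, camera adjusted p = 0.0011, adjusted p = 0.336 with an estimated correlation). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, plus strand) fell by 1.55 (SE 0.37, adjusted p = 0.00992) and Col6a2 by 2.11 (SE 0.48, adjusted p = 0.00712). The basement membrane collagen gene Col15a1, which is not on the list, fell by 3.22 (SE 0.53, adjusted p = 0.000159), the dermal matrix gene Dpt by 2.45 (SE 0.50, adjusted p = 0.00243) and Crispld2 by 2.38 (SE 0.56, adjusted p = 0.00994). The replication helicase genes Mcm3 (-1.89, SE 0.48, adjusted p = 0.0166) and Mcm7 (-1.62, SE 0.39, adjusted p = 0.0118) and the eosinophil granule gene Prg2 (-2.92, SE 0.73, adjusted p = 0.0166) fell too. Mcm3 lost its call without ligated animal 5 (-2.17 to -1.63) and Prg2 without sham animal 3 (-3.23 to -2.53). The number of lower genes went from 44 to 24 without ligated animal 5 and to 29 without sham animal 6.

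Mcm3 was the only called member of 10 proliferation genes at day 15 by either adjustment (median -0.531, camera adjusted p = 0.0128, adjusted p = 0.393 with an estimated correlation). Of 56 histone genes Hist1h4c fell (-0.76, SE 0.20, adjusted p = 0.024) and 15 were lower adjusted over the list alone (median -0.787, camera adjusted p = 2.25e-08, adjusted p = 0.339 with an estimated correlation). The call of Hist1h4c ended in 4 of 12 refits (-0.87 to -0.57). Sham animals 2 and 3 had histone shares of 0.972% (95% exact interval 0.934 to 1.01) and 1.15% (1.10 to 1.21), against 0.337 to 0.578% in the other 4 sham and 0.281 to 0.545% in the ligated animals. They also had the highest proliferation (0.113%, 0.1 to 0.127, and 0.181%, 0.161 to 0.204) and neutrophil shares of their group (0.446%, 0.420 to 0.472, and 0.342%, 0.314 to 0.373). Without both, the histone (median -0.149, camera adjusted p = 0.154), proliferation (-0.00902, 0.885) and ribosomal lists (0.0271, 0.736) did not pass, 0 histone genes were lower adjusted over the list alone, and Hist1h4c (-0.52), Mcm3 (-1.37), Prg2 (-2.4), Fn1 (1.27) and Gstm1 (1.10) lost their calls. The neutrophil (1.02, 0.00155), macrophage (0.263, 0.027) and platelet lists (0.451, 0.0163) then passed as higher, and 75 genes were lower. The B cell list was lower with 0 members called over all genes tested and 4 adjusted over the list alone (median -0.786, camera adjusted p = 0.000168, adjusted p = 0.211 with an estimated correlation). Endothelial genes (median -0.441, adjusted p = 0.00619, adjusted p = 0.393 with an estimated correlation) and heart muscle genes (median -1.06, adjusted p = 0.0109, adjusted p = 0.336 with an estimated correlation) were lower by camera, with 0 calls in each by either adjustment. The 80 ribosomal protein genes had a median of 0.111 (camera direction up, adjusted p = 0.0181, adjusted p = 0.708 with an estimated correlation), again with 0 calls. As a share of counts they went the other way, at 5.51% against 5.88% (log2 difference -0.09, exact permutation p = 0.364). Neutrophil genes (median -0.292, mean -0.202, camera direction up, adjusted p = 0.669), interferon response genes (0.137, 0.731) and platelet genes (0.359, 0.0936) did not pass. Neither did S100a8 (-0.29, SE 0.57, adjusted p = 0.838) and Pf4 (0.36, SE 0.32, adjusted p = 0.605). Without 1 library the erythroid list lost its call in 5 of 12 refits (adjusted p up to 0.304) and the ribosomal list in 5 (up to 0.222). The proliferation list lost it without sham animal 2 or 3 (up to 0.143) and the endothelial list without sham animal 1 (0.222).

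**Figure D2:**
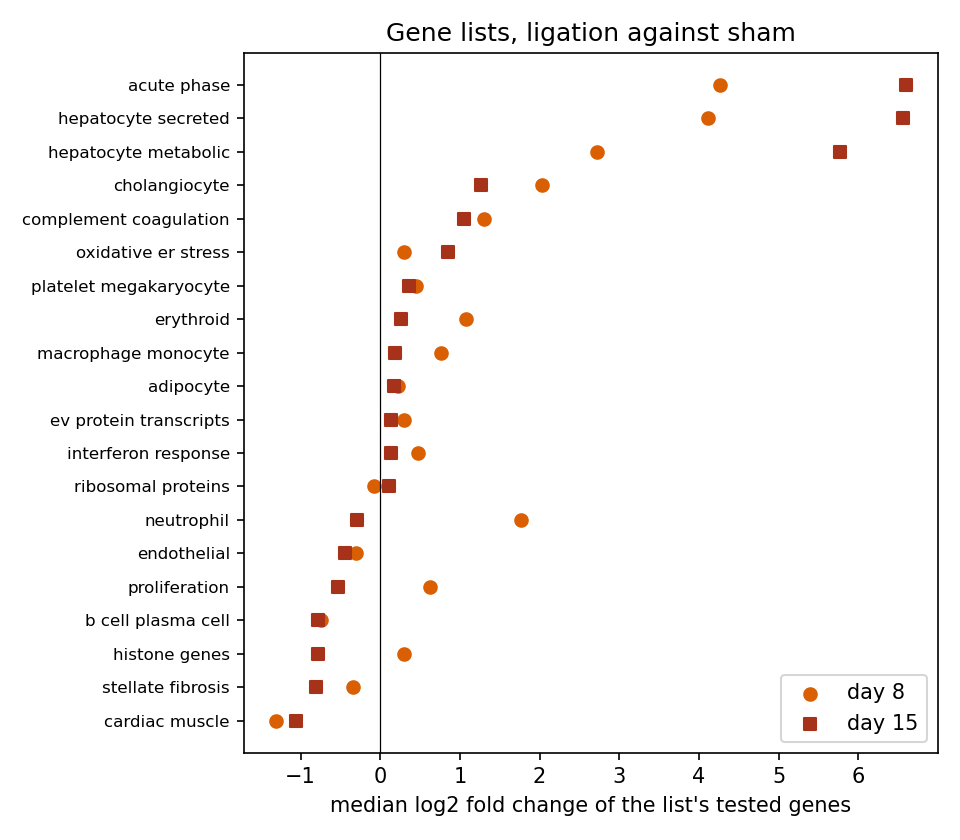
Median log2 fold change, ligation against sham, of the tested genes of 20 gene lists at day 8 (circles) and day 15 (squares). The secreted hepatocyte list has the medians 4.12 and 6.56, and the histone list 0.295 and -0.787.

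Changes at both days were compared gene by gene, which uses different animals for each day. Of the genes called at both days 52 were higher, where independent lists of these sizes share 3.96 (Fisher's exact p = 1.16e-48), and 1 was lower, against 0.161 (exact p = 0.149). Fisher's test takes genes as independent, which correlated list members are not, so these p-values do not measure the spread between animals. Across genes, which are not independent replicates, log2 fold changes correlated with r = 0.778 and rho = 0.484. Averaged over both days, 292 genes were higher and 144 lower after ligation. Tgfbi, a matrix protein induced by transforming growth factor beta and chosen after its values were seen, rose by 1.5 (SE 0.17, adjusted p = 4.94e-07). Of 10 B cell genes 6 were lower on average and 10 adjusted over the list alone (camera adjusted p = 2.32e-06, adjusted p = 0.0971 with an estimated correlation). Cd79a, a chain of the B cell receptor complex, was also chosen after its values were seen (-1.18, SE 0.32, adjusted p = 0.0159).

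**Figure D3:**
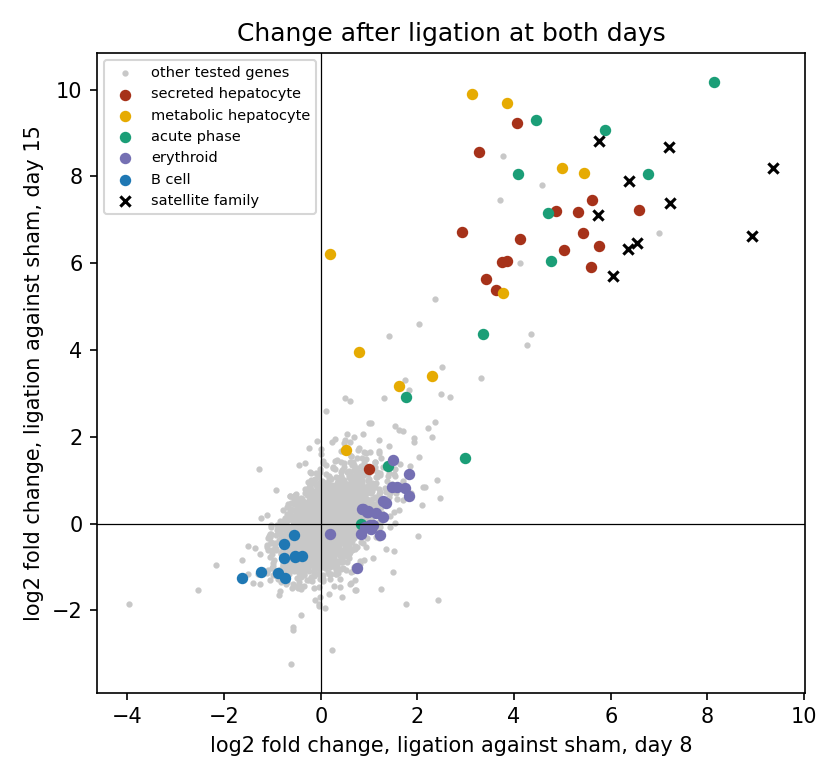
Log2 fold change after ligation at day 8 (horizontal axis) and day 15 (vertical axis) for 4112 tested genes, with members of 5 gene lists in colour and satellite family genes as crosses. Secreted and metabolic hepatocyte genes lie far to the upper right, with list medians of 4.12 and 2.72 at day 8 and of 6.56 and 5.77 at day 15.

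Whether the effect of ligation differed between days was tested as an interaction. No single gene passed (0 by edgeR, 234 at unadjusted p under 0.05, 0 by limma and 1 by DESeq2). The smallest p belonged to Chd9, which encodes a chromatin remodeller (ENSMUSG00000056608, chromosome 8, 90828352 to 91054516, plus strand), with a difference of 2.80 (SE 0.58, adjusted p = 0.177), and this was the gene called by DESeq2. Next came Tsc22d3, a glucocorticoid-induced gene (1.26, SE 0.33), Pacs2 (-1.30, SE 0.34), and the urea cycle genes Cps1 (6.02, SE 1.61) and Ass1 (3.15, SE 0.84), each with an adjusted p of 0.583. Chd9 passed when ligated animal 3 of day 8 was left out (3.32, adjusted p = 0.00157), with Trf (2.99, adjusted p = 0.0472), and when ligated animal 4 of day 15 was left out (2.98, adjusted p = 0.0412).

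By list, the difference between days was positive for secreted (median difference 1.87, camera adjusted p = 1.51e-05) and metabolic hepatocyte genes (2.90, 6.18e-06) and for ribosomal protein genes (0.172, 2.57e-07). It was negative for neutrophil (-1.95, 6.18e-06), erythroid (-0.886, 8.92e-10), macrophage (-0.448, 0.0363), interferon response (-0.439, 0.0283), proliferation (-1.31, 1.49e-06) and histone genes (-1.09, 4.56e-14). The median log2 fold change after ligation changed sign from day 8 to day 15 for ribosomal protein (-0.0779 and 0.111), neutrophil (1.77 and -0.292), proliferation (0.626 and -0.531) and histone genes (0.295 and -0.787). None of these 9 lists passed with an estimated correlation, where the adjusted p was 0.387 and 0.338 for the hepatocyte lists, 0.522 for ribosomal protein genes, and, in the order above, 0.338, 0.338, 0.372, 0.522, 0.338 and 0.338. With fry 0 lists passed. In the day 8 libraries 1 to 3 alone, the median change after ligation was 5.76 for secreted and 5.13 for metabolic hepatocyte genes. In libraries 4 to 6 alone the medians were 3.54 and 1.77, and at day 15 they were 6.56 and 5.77. The size of the hepatocyte difference between days thus depended on which day 8 libraries were used. Without sham animals 2 and 3 of day 15 the neutrophil (adjusted p = 0.11), macrophage (0.315) and interferon lists (0.0566) no longer passed by camera. The differences that still passed were smaller for erythroid (-0.291, 0.0248), proliferation (-0.613, 0.0353), histone (-0.42, 0.00523) and ribosomal protein genes (0.0967, 0.00523). The stellate cell (-0.809, 0.0248), endothelial (-0.607, 0.0491) and stress lists (0.361, 0.0248) then passed.

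Within ligated animals, day 15 against day 8, hepatocyte transcripts were higher. Kng1, which encodes kininogen, rose by 3.74 (SE 0.58, adjusted p = 0.000952), Rbp4, the retinol carrier, by 3.76 (SE 0.60, adjusted p = 0.00101), Serpina1b by 3.29 (SE 0.51, adjusted p = 0.000952) and Serpina3k by 3.10 (SE 0.51, adjusted p = 0.00188). Chd9 rose by 2.74 (SE 0.40, adjusted p = 0.000767), from 423 ± 324 to 2798 ± 1879 CPM (SD, n = 6). In all, 93 genes were higher and 86 lower (edgeR, 706 at unadjusted p under 0.05). Secreted hepatocyte genes rose in 15 of 17 cases, 16 adjusted over the list alone (camera adjusted p = 1.21e-24, adjusted p = 0.0345 with an estimated correlation). Acute phase genes rose in 9 of 12 by either adjustment (camera adjusted p = 3.4e-13, adjusted p = 0.0345 with an estimated correlation). Metabolic hepatocyte genes rose in 9 of 10 cases, 10 adjusted over the list alone (camera adjusted p = 6.59e-12, adjusted p = 0.0605 with an estimated correlation). By camera the bile duct (median 1.24, adjusted p = 0.012), stress (0.675, 0.00054) and ribosomal protein lists (0.228, 9.23e-11) were also higher. The erythroid (-0.69, 3.53e-07), interferon (-0.598, 9.96e-06), B cell (-0.45, 0.0217), proliferation (-0.498, 0.012) and histone lists (-0.444, 0.000606) were lower. None of these 8 passed with an estimated correlation (adjusted p = 0.133 to 0.494). Platelet genes fell in 12 of 26 cases, 25 adjusted over the list alone (median -1.5, camera adjusted p = 3.12e-14, adjusted p = 0.243 with an estimated correlation). The platelet share was 0.370% at day 15, against 0.400% in the day 8 libraries 1 to 3 (log2 difference -0.04, exact permutation p = 0.893) and 1.81% in the deeper libraries 4 to 6 (-2.24, exact permutation p = 0.0119), and over all 6 the difference was -1.14 (exact permutation p = 0.0823). The hepatocyte share was higher at day 15 than in either part (log2 differences 2.32, SE 0.835, and 3.27, SE 0.513, exact permutation p = 0.0357 and 0.0119). With a term for the deeper libraries 4 to 6 of day 8, 3 genes were called: Chd9 (2.45, adjusted p = 0.00619), Kdm3a (1.78, adjusted p = 0.0397) and Matr3 (1.20, adjusted p = 0.044), named after their values were seen. Kng1, Rbp4, Serpina1b and Serpina3k then had 2.51, 2.82, 2.42 and 2.22 without a call. Without 1 ligated animal the count of 179 ranged from 37 (without number 5 of day 15) to 336 (without number 3 of day 8). It was 71, 96 and 114 without numbers 1, 2 and 4 of day 15 and 41, 45 and 77 without numbers 4, 5 and 6 of day 8.

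Within sham animals, day 15 against day 8, 0 genes passed by edgeR (439 at unadjusted p under 0.05; 0 by limma and 5 by DESeq2). The smallest p belonged to the lamin B receptor gene Lbr (1.41, SE 0.29), the platelet receptor gene P2ry12 (-2.33, SE 0.53), the metalloproteinase gene Mmp19 (-2.71, SE 0.62), Pttg1ip (-1.79, SE 0.41) and the integrin gene Itgb5 (-1.91, SE 0.44), each with an adjusted p of 0.146; these were the 5 called by DESeq2. Lbr passed without sham animal 4 of day 15 (1.58, adjusted p = 0.0244), and Mmp19, P2ry12, Itgb5 and Pttg1ip without sham animal 3 of day 8 (adjusted p = 0.0496 each). By list, platelet genes were lower at day 15 (median -1.22, camera adjusted p = 4.77e-17, adjusted p = 0.463 with an estimated correlation) and neutrophil genes higher (1.92, 1.39e-05, adjusted p = 0.463 with an estimated correlation), with 25 and 8 called adjusted over the list alone. Histone (0.595, 7.64e-07), proliferation (0.571, 0.00809), endothelial (0.535, 0.00809) and adipocyte genes (0.437, 0.0271) were also higher and B cell genes lower (-0.344, 0.00809) by camera, with 0 genes called by either adjustment and none passing with an estimated correlation (adjusted p = 0.463 to 0.619). Without sham animals 2 and 3 of day 15 the histone (0.826), proliferation (0.89), adipocyte (0.334) and B cell lists (0.106) did not pass, and the stellate cell (0.56, 0.00269), erythroid (-0.359, 0.00592) and ribosomal lists (0.136, 0.00204) did. As a share of counts neutrophil genes held 0.183% against 0.0646% (log2 difference 1.20, exact permutation p = 0.201), and without sham animals 2 and 3 of day 15, the highest of their group, the list did not pass (median 0.46, camera adjusted p = 0.347). Against the day 8 libraries 1 to 3 the platelet share differed by -0.14 on the log2 scale (exact permutation p = 0.631), and against libraries 4 to 6 by -2.04 (exact permutation p = 0.0119). The hepatocyte share did not differ beyond the spread between animals (log2 difference 0.36, SE 0.28, exact permutation p = 0.227).

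A family of predicted genes that resemble satellite DNA, tandem repeats of centromeric regions, was chosen after its values were seen. The family has 12 members, on chromosomes 2, 9 and 14. Their longest matches to the members Gm10800 or Gm10801 had 90.6% or more sequence identity. It held 4.18% ± 4.51 of the counts after ligation and 0.0204% ± 0.0145 after sham surgery at day 15 (log2 difference 6.93, SE 1.02, exact permutation p = 0.00216, n = 6 each). At day 8 it held 5.27% ± 12.6 and 0.0226% ± 0.00986 (log2 difference 2.61, SE 2.12, exact permutation p = 0.284, and 0.0173 for the difference of the percentages), with 5 of 6 ligated animals above all sham animals and 1 below. Ligated animal 3 of day 8 alone had 30.9% (95% exact interval 30.8 to 31.1), and ligated animal 6 of day 8 had 4 counts. Chemosensory receptor genes, which are silent in blood and liver, were higher in the same comparison at day 15 (0.112% against 0.00179%, log2 difference 5.72, SE 0.73, exact permutation p = 0.00216). The family made up 8 of the higher calls at day 8 and 10 at day 15. Gm10800 (ENSMUSG00000075014, chromosome 2, 98666547 to 98667301, minus strand) rose by 9.36 (SE 1.87, adjusted p = 0.00673) at day 8. This call ended without ligated animal 3 (3.08), with the replicate block (4.11) and with the term for day 8 libraries 4 to 6 (5.865). Without the 3 ligated animals with over 5% of counts in the family, 72 genes were higher and 12 lower at day 8, and 120 and 32 at day 15.

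**Figure D4:**
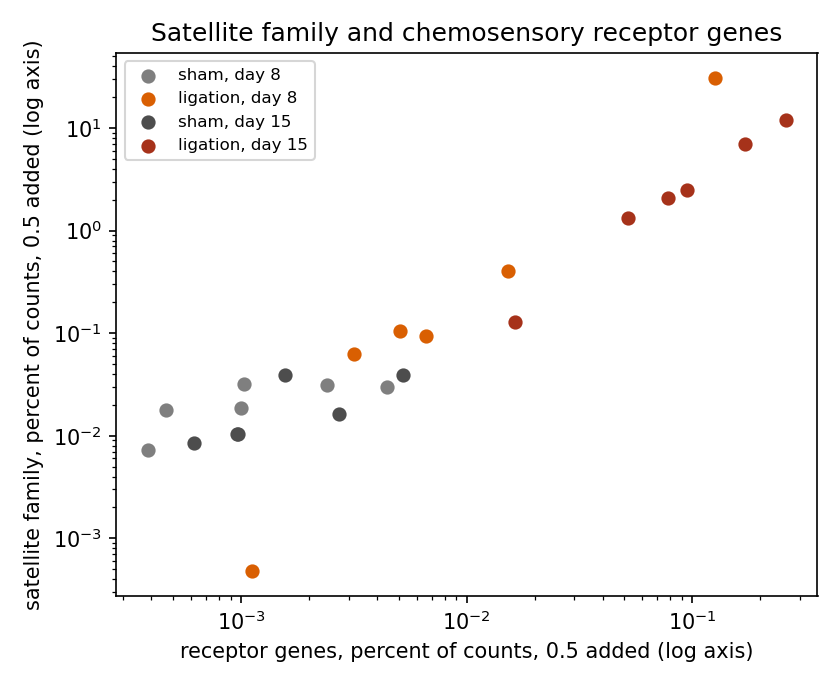
Share of counts in chemosensory receptor genes (horizontal axis) and in the satellite family (vertical axis), in percent on log axes after adding 0.5 counts, for the 24 animals of the 4 groups. Both shares are highest in ligated animals, with satellite family means of 4.18% at day 15 against 0.0204% in sham animals.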

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

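The tests of abundant genes and of depth for the hepatocyte share, of divided reads, of 1 library and of tied zeros for the satellite family, without sham animals 2 and 3 of day 15, and of the day 8 batch for platelet transcripts were chosen only after the result was seen.

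In 20 of 180 groups of 6, 1 library lay far from the rest by its gap to the nearest value as a share of the group's range, where chance marks about 1 in 20 groups. Ligated animal 3 of day 8 stood apart in Lars2 (31.6%, 95% exact interval 31.5 to 31.8, against 43.5 to 48.3%, gap 0.754) and in the hepatocyte share (0.512%, 0.487 to 0.538, against 0.0679 to 0.126%, gap 0.695). The same library had 480.5 CPM of Apob against 42.4 to 108 (gap 0.629), 1700 of Trf against 196 to 396 (0.678), 222 of Bhmt against 9.58 to 30.0 (0.684) and 15.8 of Ccr2 against 41.1 to 57.5 (0.721). Among other ligated animals, number 4 of day 8 had 69.8 CPM of Tyrobp against 104 to 121 (0.717), number 5 of day 15 had 187 of Gstm3 against 38.0 to 64.9 (0.676), number 3 of day 15 had 0 of Col6a2 against 6.48 to 13 (0.643), and number 1 of day 15 had 76.4 of Xpo7 against 229 to 433 (0.628). Among sham animals, number 6 of day 15 had 64.1 CPM of C4b against 18.5 to 28.9 (0.661), number 1 of day 8 had 9.56 of Pzp against 0 to 1.27 (0.793), number 2 of day 8 had 3.52 of Col2a1 against 28.9 to 65.8 (0.647), and number 3 of day 8 had 323 of Rflnb against 76.5 to 120 (0.695). In 6 sham cases only 1 library had any count, which makes the gap 1: Hpx and Fgb in number 5 and Itih4 in number 6 of day 15, and Apob in number 6, Hpx in number 2 and Serpina1b in number 3 of day 8.

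The effect of ligation differed between days for 9 lists by camera with the preset correlation, and for none with an estimated one (smallest adjusted p = 0.338). The adjusted p was 1.51e-05 for secreted and 6.18e-06 for metabolic hepatocyte genes and 2.57e-07 for ribosomal protein genes, all with higher values at day 15. It was 0.0363 for macrophage, 6.18e-06 for neutrophil, 8.92e-10 for erythroid, 0.0283 for interferon response, 1.49e-06 for proliferation and 4.56e-14 for histone genes, all with lower values at day 15. Without sham animals 2 and 3 of day 15, the macrophage (adjusted p = 0.315), neutrophil (0.11) and interferon lists (0.0566) no longer passed. The median difference of erythroid genes then went from -0.886 to -0.291 (adjusted p = 0.0248), of proliferation genes from -1.31 to -0.613 (0.0353) and of histone genes from -1.09 to -0.42 (0.00523), and stellate cell (0.0248), endothelial (0.0491) and stress lists (0.0248) passed. The hepatocyte share differed too (permutation p = 0.016), by a test whose arrangements assume that the permuted labels have no effect at all. The day 8 medians of secreted hepatocyte genes were 5.76 in libraries 1 to 3 and 3.54 in libraries 4 to 6, against 6.56 at day 15. Those of metabolic hepatocyte genes were 5.13 and 1.77, against 5.77 at day 15.

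Hepatocyte transcripts were higher in all ligated animals at both days. Against genomic DNA as their source, the share expected from counts per exon length of chemosensory receptor genes was 0.407% of the measured share in the median ligated library of day 15. Leaving hemoglobin, Lars2 and satellite genes out of the denominator gave a day 15 log2 difference of 5.23 (SE 0.435), which argues against abundant genes as the cause. The 3 sham libraries deeper than every ligated library of day 15 reached at most 0.0278%, below the lowest ligated value of 0.392%, which argues against depth. These 3 were the day 8 libraries 4 to 6, which stood apart in platelet transcripts too, so this comparison crosses days. Within day 15, the deepest sham library (number 4, 351201 counts) had 0.0196%. The less deep ligated libraries 1 (315404 counts) and 3 (331654 counts) had 1.40% and 0.481%. Release of hepatocyte RNA into plasma after ligation is a candidate explanation, and whether that RNA lay inside vesicles or came free from damaged cells was not tested.

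Satellite family transcripts were higher after ligation at day 15. Their share rose with that of a second set of 133 genes that are silent in liver and blood (keratin-associated proteins, beta-defensins and bitter taste receptors), with rho = 0.93 over the 12 ligated libraries (permutation p = 5e-05), or 0.883 with the 4 libraries without a count tied (permutation p = 0.00034, 40 counts in all), which is consistent with genomic DNA in these libraries. Reads divided among near-identical copies would leave the family total alike in both groups, and that total differed by 6.93 on the log2 scale. Against 1 library as the cause, the lowest ligated share at day 15 (0.128%, 95% exact interval 0.117 to 0.141) lay above the highest sham share (0.0390%, 0.0312 to 0.0481). Without the highest library the exact permutation p was 0.00216, the smallest that 5 against 6 can give. That p follows from the order of the shares and adds nothing to it. DNA released after ligation and a difference in sample handling stay open, and transcription of satellite repeats was not tested separately.

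Platelet transcripts were lower at day 15 than at day 8 in sham animals. Against the day 8 libraries 1 to 3 alone, the log2 difference of the platelet share was -0.135 (SE 0.388, exact permutation p = 0.631), and against libraries 4 to 6 it was -2.04 (exact permutation p = 0.0119). This is consistent with a batch or handling difference among the day 8 libraries rather than a change with time. The same split was seen in ligated animals of day 8, at 0.400% and 1.81%. A biological difference between days was not tested apart from this split.

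Other splits of the libraries were refitted to ask whether chance can be excluded. At day 8, 2 of 100 splits gave as many genes, the real one (129) included. The highest other (137) put 5 of the 6 deeper libraries numbered 4 to 6 on 1 side, and with the replicate block 163 genes were called. Of the 32 day 8 splits that part all 6 numbers, 1 gave as many, the real one, and the highest other gave 4. Splits that mix the real groups carry the real difference as spread, so their counts are not those of data without any difference. So many calls were rare among other splits, which argues against chance but does not exclude it. The same holds for day 15 (1 of 100, real 187, highest other 70), the average of both days (1 of 100, 436, 20) and ligation day 15 against day 8 (1 of 100, 179, 54). For the last of these, a term for the deeper day 8 libraries 4 to 6 left 3 calls. Against the day 8 libraries 1 to 3 alone the hepatocyte share still differed by 2.32 (SE 0.835, exact permutation p = 0.0357), where all 6 gave 2.80 (SE 0.592), while the platelet share differed by -0.04 (SE 0.404, exact permutation p = 0.893), so that batch alone does not account for the hepatocyte difference and stays open for platelet genes. Chance could not be excluded for the difference between days, where 24 of 100 splits gave as many genes at unadjusted p under 0.05 (real 234, highest other 635), nor for sham day 15 against day 8 (11 of 100, 439, 633).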

How the results depend on the processing

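The term for the day 8 libraries 4 to 6, the block within days, removal of satellite genes, of 3 libraries rich in them or of sham animals 2 and 3 of day 15, thinning, and the day 8 libraries 1 to 3 or 4 to 6 alone were chosen only after the result was seen.

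The hepatocyte share kept its direction under every setting run, at an exact p of 0.1 with 3 against 3 and 0.0312 by sign flips within numbers. With RLE size factors 40 of 40 list results and 94 of 97 named gene results kept their side of the threshold. Without a filter, which tests 18710 genes, 263 and 35 genes were higher and lower at day 8 and 553 and 135 at day 15, with 1041 for the average, 51 for the difference between days, 652 between days after ligation and 150 after sham surgery. With the strict filter, which tests 3101 genes, 77 were higher at day 15 and 85 differed between days after ligation. DESeq2 gave 24 lower genes at day 8, 1 for the difference between days and 5 for sham time; limma gave 25 lower genes at day 8 and 350 between days after ligation. The estimated correlation left 3 and 4 lists at day 8 and day 15, and fry 7 at day 15. With the term for day 8 libraries 4 to 6, 25 genes were lower at day 8, 82 were lower at day 15, 1 differed between days (Chd9) and 3 changed with time after ligation. At day 8 Gm10800 then lost its call (5.865) and S100a8 gained one (2.137). Without the 3 satellite-rich libraries 72 genes were higher at day 8 and 1 differed between days (Chd9). Thinning to the smallest total, a loss of depth, gave 28 higher and 3 lower genes at day 8 (Ets1, Kif21b and Gimap1), 95 and 20 at day 15, 196 for the average and 56 between days after ligation. Day 8 libraries 1 to 3 alone gave 3 lower genes (Map4, Itpkb and Gm20716) and libraries 4 to 6 alone 16 higher and 2 lower (Spib and Col2a1). Genes in parentheses were named after their values were seen. Apart from fewer genes, libraries or counts, the cause was not tested.

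The replicate block, whose numbers met the pairing criterion at day 8, gave 24 lower genes there. S100a8 gained a call (2.09), the endothelial list gained one (adjusted p = 0.0252), and Pln (-2.08) and Gm10800 (4.11) lost theirs. It changed no other call at day 8 among the named genes and lists. At day 15, where the numbers share only a name, uncalled values reversed to 0.0678 for S100a8 and 0.0104 for Hbb-bs. A block within days gave 33 lower genes at day 8, 71 lower at day 15 and 1 for the difference between days (Chd9), with S100a8 at 0.31 at day 15.

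Other reversals concerned results without a call at day 15. S100a8 was 0.67 with limma. Hbb-bs was 0.17 without the 3 satellite-rich libraries. Without sham animals 2 and 3 of day 15 S100a8 was 1.25 and Hbb-bs 0.15, 75 genes were lower at day 15, and 1 gene (1700027J19Rik) changed with time after sham surgery. Without 1 library, S100a8 ranged from -0.56 to 0.36 and Hbb-bs from -0.19 to 0.21. The interferon list turned without ligated animal 4 (adjusted p = 0.943, range 0.486 to 0.943) and the neutrophil list without sham animal 4 (adjusted p = 0.523, range 0.0673 to 0.99). Without 1 library the counts ranged from 52 to 136 higher and 4 to 16 lower at day 8, 100 to 171 and 24 to 59 at day 15, 357 to 515 for the average, 0 to 2 for the difference between days, 37 to 336 between days after ligation and 0 to 4 after sham surgery (1 of them 1700027J19Rik, without sham animal 2 of day 15), with 12 to 17 lists at day 8 and 11 to 15 at day 15.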

Other observations

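The share tests of gene lists, also per effective library size, the rank correlation with zeros tied, the counts set against receptor genes, the genes named here and the comparison of acute phase with secreted genes were chosen only after the result was seen.

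Transcripts of the intestinal epithelium list and of bile acid handling, whose genes were all too rare for single tests, were higher after ligation as shares of counts. Intestinal genes held 0.00559% against 0.00140% at day 8 (log2 difference 2.28, SE 0.63, exact permutation p = 0.00866, adjusted 0.026 over 27 lists). At day 15 they held 0.0126% against 0.000971% (3.68, SE 0.53, exact permutation p = 0.00216, adjusted 0.00835), with all 6 ligated animals above all sham animals. Much of the list's rise at day 15 lay in Anpep (70 counts against 7), Mttp (52 against 3) and Apoa4 (20 against 0), which liver also expresses, and the hepatocyte share rose alongside (1.20% against 0.0271%). Chemosensory receptor genes rose in the same libraries (0.112% against 0.00179%), and their counts per exon length would give 29 of the 284 intestinal counts after ligation at day 15 (10.2%) and 4.33% of the 134 at day 8. For bile acid handling genes the shares were 5.22% of 876 counts and 3.67% of 250. Fabp2, the intestinal fatty acid binding protein, had 22 counts against 0 at day 8 and 36 against 0 at day 15, and Alpi, intestinal alkaline phosphatase, had 9 against 0 and 10 against 0. Bile acid handling genes held 0.00866% against 0.00451% at day 8 (0.89, exact permutation p = 0.00649, adjusted 0.025) and 0.0367% against 0.00537% at day 15 (2.46, exact permutation p = 0.00216, adjusted 0.00835). Abcb11, the bile salt export pump, had 15 counts against 0 and 70 against 1, and Abcc2, an exporter of conjugated bilirubin, had 9 against 2 and 103 against 1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 3 counts against 5 at day 8 and 49 against 0 at day 15. Saa1 had 30 counts against 0 at day 15.

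Lymphocyte transcripts took smaller shares at day 8. T and NK cell genes held 0.0204% ± 0.00451 after ligation and 0.0328% ± 0.00459 after sham surgery (SD, n = 6, log2 difference -0.70, exact permutation p = 0.00216, adjusted 0.00974), and at day 15 the log2 difference was 0.14 (exact permutation p = 0.66). Whether the days differ was not tested for this list. B cell genes held 0.0620% against 0.121% at day 8 (exact permutation p = 0.00216, adjusted 0.00974), and ribosomal protein genes 4.57% against 5.93% (exact permutation p = 0.00216, adjusted 0.00974). These shares depend on what else was counted. Per TMM effective library size, the day 8 log2 differences were -0.38 for T and NK cell genes (SE 0.127, exact permutation p = 0.013), -0.65 for B cell genes (SE 0.163, exact permutation p = 0.00649) and -0.06 for ribosomal protein genes (SE 0.0911, exact permutation p = 0.515), without adjustment over lists. Skeletal muscle (log2 differences -0.69 and -1.10 at day 8 and day 15, adjusted exact p = 0.23 and 0.0828), exocrine pancreas (0.06 and 1.69, 0.904 and 0.0854) and immunoglobulin genes (-0.68 and -0.86, 0.423 and 0.321) did not pass. Lars2, annotated as protein coding and the only gene of the structural RNA list in the table, held 43.5% against 48.1% at day 8 and 47.8% against 48.9% at day 15 (adjusted exact p = 0.108 and 0.668 on the log2 scale).

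Chd9 and P2rx4, which encodes an ATP-gated ion channel, rose at both days. Chd9 rose by 2.37 (SE 0.41, adjusted p = 0.00226) at day 8 and by 5.18 (SE 0.46, adjusted p = 3.01e-08) at day 15, from 77.0 ± 24.7 CPM to 2798 ± 1879 (SD, n = 6). P2rx4 rose by 4.27 (SE 0.75, adjusted p = 0.00238) and 4.11 (SE 0.64, adjusted p = 8.25e-05). Gm20594, 88.4% identical to the mitochondrial ribosomal RNA gene mt-Rnr2 over 439 bp, rose by 1.42 (adjusted p = 0.0402) at day 8 and had 0.62 (adjusted p = 0.416) at day 15.

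Chemosensory receptor genes, which are silent in liver and blood, held 0.0259% against 0.00144% at day 8 (log2 difference 2.80, exact permutation p = 0.0195) and 0.112% against 0.00179% at day 15 (5.72, SE 0.73, exact permutation p = 0.00216). In a family of 12 relations, their share followed that of the satellite family over 12 ligated libraries with r = 0.944 and rho = 0.965 (permutation p = 1e-05 each, the smallest possible, adjusted 0.00012). Without the 2 farthest libraries r was 0.938. Within ligated animals r was 0.965 at day 8 and 0.994 at day 15 (exact p = 0.00278 and 0.00139, adjusted 0.00833 and 0.00556), with rho of 0.943 and 1 (exact p = 0.0167 and 0.00278, adjusted 0.025 and 0.0111). In sham animals r was 0.703 and rho 0.713 (permutation p = 0.0119 and 0.0116, adjusted 0.0204 and 0.025), and r was 0.596 without the 2 farthest.

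The second set of silent genes followed the satellite family over the ligated libraries with r = 0.86 (permutation p = 0.00017, adjusted 0.00102) and rho = 0.93 (permutation p = 5e-05, adjusted 3e-04), and r was 0.79 without the 2 farthest. These values had 0.5 counts added per library, and with the 4 libraries without a count tied rho was 0.883 (permutation p = 0.00034). At day 15, where the ligated libraries had 1 to 13 counts, r was 0.736 (exact p = 0.0833, adjusted 0.111) and rho 0.943 (exact p = 0.0167, adjusted 0.025), and r was 0.828 without the 2 farthest. In ligated animals of day 8 and in sham animals, 4 of 6 and 10 of 12 libraries had 0 counts in the set (4 and 2 counts in all), too few to read a relation or its absence. The values there were r = 0.91 and rho = 0.943 (exact p = 0.0111 and 0.0167, adjusted 0.0204 and 0.025) and r = 0.0792 and rho = 0.035 (permutation p = 0.806 and 0.921, which are also the adjusted values), with r of 0.696 and 0.468 without the 2 farthest. The hepatocyte share followed the satellite share over the ligated libraries with r = 0.686 and rho = 0.783 (permutation p = 0.0117 and 0.00401, adjusted 0.0204 and 0.012), and r was 0.741 without the 2 farthest. Within day 8 and day 15, with 6 libraries each, r was 0.693 and 0.502 (exact p = 0.143 and 0.294, adjusted 0.172 and 0.321) and rho 0.429 and 0.543 (exact p = 0.419 and 0.297, adjusted 0.458 and 0.357), which did not pass. Without the 2 farthest r was 0.492 and 0.856. In sham animals r was 0.52 and rho 0.566 (permutation p = 0.0834 and 0.0584, adjusted 0.111 and 0.0778), and 0.523 without the 2 farthest.

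Whether the liver's inflammatory response raised acute phase transcripts beyond the general rise of hepatocyte RNA was tested as a hypothesis. The median day 15 changes of 12 acute phase and 17 secreted genes differed by 0.0378 on the log2 scale (medians 6.60 and 6.56, p = 0.945 by permutation of list membership over genes), and no excess was seen among them. Genes are not independent replicates, so this p does not measure the spread between animals. Members of both lists, such as Fgg and Serpina3k, had no count in sham libraries, and Saa1 was below the filter. The comparison therefore cannot settle whether such an excess exists.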
